A study of Homo sapiens with 20 samples.

How the data were processed

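RNA sequencing measured gene expression in immortalized human pericytes (a line from Celther), the contractile mural cells of small vessels. Per the labels, cells were left untreated or were given recombinant human eNAMPT at 500 ng/mL, recombinant human PDGF-BB at 20 ng/mL, or both, for 4 hours. There were 5 replicates in each of 4 groups, 20 libraries in all.

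Per the labels, the authors used FastQC 0.11.7, STAR 2.6.1a, featureCounts 1.6.4 and DESeq2 1.18.1 with the GRCh38 assembly. The deposited table holds raw gene counts for each library, with no normalization. It also holds 4 columns of summed counts, which equalled the sums of the 5 libraries of each group exactly. In the same table the authors gave a log2 fold change and an adjusted p-value for each pairwise comparison. A further deposited table of counts was never lower than the first in any cell and was higher in 152335 cells. Among genes with 50 or more counts there, 77.9% had at least 95% of those counts in the first table. What separates the counts of these tables is not stated. The first table was used here, and the other served as an alternative.

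All 58676 gene identifiers matched GENCODE 29, and 58639 had the same chromosome and start there, so positions are those of GENCODE 29 on GRCh38. The 92 ERCC and 7 SIRV spike-in transcripts were left out of the gene tests. Genes were filtered with filterByExpr of edgeR 4.0.16 at its default settings, which kept 12111 genes, and libraries were scaled by TMM. One quasi-likelihood model (glmQLFit and glmQLFTest, two-sided) was fitted to all 20 libraries with a mean for each group. It gave 5 pairwise comparisons and the interaction, the difference between the eNAMPT effect with and without PDGF-BB on the log2 scale. P-values were adjusted by Benjamini-Hochberg within each of the 6 comparisons, and a gene passed at an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Expression levels are CPM, counts scaled to 1e6 per library, after TMM, as mean ± SD over 5 libraries.

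Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera with a correlation estimated for each list and the rotation test fry were run beside it. With the preset correlation, libraries regrouped at random often passed lists too, as given with the flagged results. The 25 lists covered immediate early genes, ERK output and feedback, NF-kB and inflammatory genes, interferon-induced genes, cholesterol synthesis, entry into S phase, mitosis, pericyte markers, contractile genes, extracellular matrix, matrix proteolysis, angiogenic factors, NAD metabolism, receptors, Notch, TGF-beta and BMP targets, FOXO targets, ATF4 and unfolded protein targets, glycolysis and hypoxia, and ribosome biogenesis. The last 5 held markers of endothelial cells, leukocytes, epithelial cells, fibroblasts and neural or glial cells. The 21 lists with at least 5 tested members were tested, and p-values were adjusted over them within each comparison.

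The groups, comparisons, gene lists, tests, thresholds and most alternatives were chosen before the data were examined, as was the rule for genes named individually. That rule took genes with a mean log2 CPM of at least 1 that passed and whose 5 treated libraries all lay on one side of the mean of the compared group. In each pairwise comparison it kept the 10 with the largest rise and the 10 with the largest fall. Where fewer than 10 passed, it took all that passed and the 5 with the smallest p that did not. It added up to 4 members of each list with the smallest p, the 10 smallest p of the interaction, and a few fixed genes, among them NAMPT, PDGFRB, PDGFRA and TLR4. Genes named outside this rule are identified where they appear.

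The alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, 2 other filters, the replicate number as a term, fits of only the groups compared, a threshold of 0.01, a minimum absolute log2 fold change of 1, and leaving out each library. The other count table and scaling by spike-in counts were added after the data were seen. The analysis ran in R 4.3.3. Tested on simulated data with 5 libraries in each group, the model recovered 52% of 50 genes set to an absolute log2 fold change of 0.5, 76% at 1, 94% at 1.5 and 96% at 2. It made 9 false calls among the unchanged genes. Genes of all these sizes were changed at once, and the simulated libraries shared no variation by replicate number. In the data 9 genes passed with eNAMPT, fewer than were recovered here, so these shares need not hold for the eNAMPT comparisons.

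Gene counts ranged from 2894878 to 4011066 per library. Fold changes of genes with a few counts per library are correspondingly imprecise.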

Results

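The series holds 20 RNA sequencing libraries of immortalized human pericytes, made to examine how extracellular NAMPT acts on these cells. eNAMPT is the secreted form of the NAD salvage enzyme nicotinamide phosphoribosyltransferase, and PDGF-BB is the growth factor that binds the pericyte receptor PDGFRB. The 4 groups of 5 libraries were control cells and cells given eNAMPT, PDGF-BB or both for 4 hours. Mean gene counts were 3202402 ± 317303 (SD, n = 5) in control, 3270587 ± 246521 with eNAMPT, 3440523 ± 203824 with PDGF-BB and 3363709 ± 464375 with both. Mitochondrial genes took 9.15% ± 0.472 of counts in control, 9.07% ± 0.400 with eNAMPT, 8.67% ± 0.284 with PDGF-BB and 8.60% ± 0.232 with both. Over 15 exact permutation tests (two-sided) of library measures against control, the smallest Benjamini-Hochberg adjusted p was 0.476.

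The cells carried transcripts of the receptors that the treatments are known to engage. PDGFRB stood at 133 CPM ± 11.4 (SD, n = 5) in control cells, and PDGFRA, the related receptor, at 97.8 CPM ± 12.5. TLR4, described as a receptor of eNAMPT, stood at 37.2 CPM ± 4.46. None of PDGFRB, PDGFRA and TLR4 passed in any of the 6 comparisons (edgeR quasi-likelihood). The smallest unadjusted p among them was 0.00164, for PDGFRA between both treatments and PDGF-BB alone, at a log2 fold change of -0.37 with an adjusted p of 0.865. NAMPT, the intracellular enzyme's gene, stood at 64.5 CPM ± 6.48 in control and 66.6 CPM ± 4.61 with eNAMPT.

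The first comparison asked what eNAMPT alone did within 4 hours. Genes of inflammatory signalling rose and none fell. CXCL1, a neutrophil chemokine (ENSG00000163739, chromosome 4, 73869393 to 73871242), went from 13.4 CPM ± 2.53 to 52.8 CPM ± 6.48 (SD, n = 5). CXCL8, interleukin 8 (ENSG00000169429, chromosome 4, 73740506 to 73743716), went from 42.5 CPM ± 10.7 to 139 CPM ± 32.6. The adhesion molecule VCAM1 (ENSG00000162692, chromosome 1, 100719742 to 100739045) went from 14.6 CPM ± 5.33 to 42.4 CPM ± 4.76. The monocyte chemokine CCL2 (ENSG00000108691, chromosome 17, 34255218 to 34257203) doubled from 166 CPM ± 34.5 to 334 CPM ± 62.0, and NFKBIA, which encodes the NF-kB inhibitor IkB-alpha (ENSG00000100906, chromosome 14, 35401511 to 35404749), from 132 CPM ± 10.6 to 266 CPM ± 10.1.

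With eNAMPT, 9 genes rose and 0 fell of 12111 tested (edgeR quasi-likelihood, adjusted p under 0.05), with 437 at an unadjusted p under 0.05, fewer than the 606 expected if no gene differs. This shortfall was absent with replicate number as a term in the model, where 21 genes passed and 659 had an unadjusted p under 0.05. DESeq2 passed 14 genes, of which 1 fell, and limma-voom passed 9, all higher. The log2 fold change was 1.98 (SE 0.16, adjusted p 4.3e-12) for CXCL1, 1.72 (SE 0.14, 2.37e-11) for CXCL8, 1.53 (SE 0.17, 7.25e-08) for VCAM1, 1.01 (SE 0.11, 7.25e-08) for CCL2 and 1.01 (SE 0.08, 1.55e-12) for NFKBIA. TNFAIP3, the NF-kB inhibitor A20, rose by 1.19 (SE 0.20, adjusted p 0.00117), the soluble pattern receptor PTX3 by 0.81 (SE 0.14, 0.00132) and the immediate early gene IER3 by 0.60 (SE 0.09, 0.000181). BIRC3, an inhibitor of apoptosis, rose by 1.03 (SE 0.19, 0.00522), and its call ended without control replicate 4 (0.94, adjusted p 0.0506) or eNAMPT replicate 5 (0.81, 0.0967). For each of the 9 genes, 5 of 5 eNAMPT libraries lay above the control mean. Of genes that did not pass, the chemokine CXCL3 had a log2 fold change of 1.38 (adjusted p 0.0569), CXCL6 2.36 (0.0582) and EGR1 0.45 (0.0981).

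Of the 28 tested members of the NF-kB and inflammatory list, 7 rose with eNAMPT over all genes and 20 when adjusted over the list alone, and 0 fell. The median log2 fold change of the list was 0.82, and its adjusted p was 4.99e-49 by camera and 3.29e-07 with an estimated correlation. The interferon list had a median of 0.12 and 0 of 21 members passing over all genes, with 1 higher when adjusted over the list alone. Its adjusted p was 0.0031 by camera but 0.762 with an estimated correlation. That interferon call also ended without control replicate 3 (adjusted p 0.217), control replicate 5 (0.0728), eNAMPT replicate 2 (0.0658) or eNAMPT replicate 4 (0.141). The ERK output and feedback list had a median of -0.14 and an adjusted p of 0.0688, and it passed without eNAMPT replicate 2 (0.0106), control replicate 4 (0.00292) or eNAMPT replicate 5 (0.0224). The other 18 tested lists had adjusted p of 0.204 to 0.987.

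**Figure D1:**
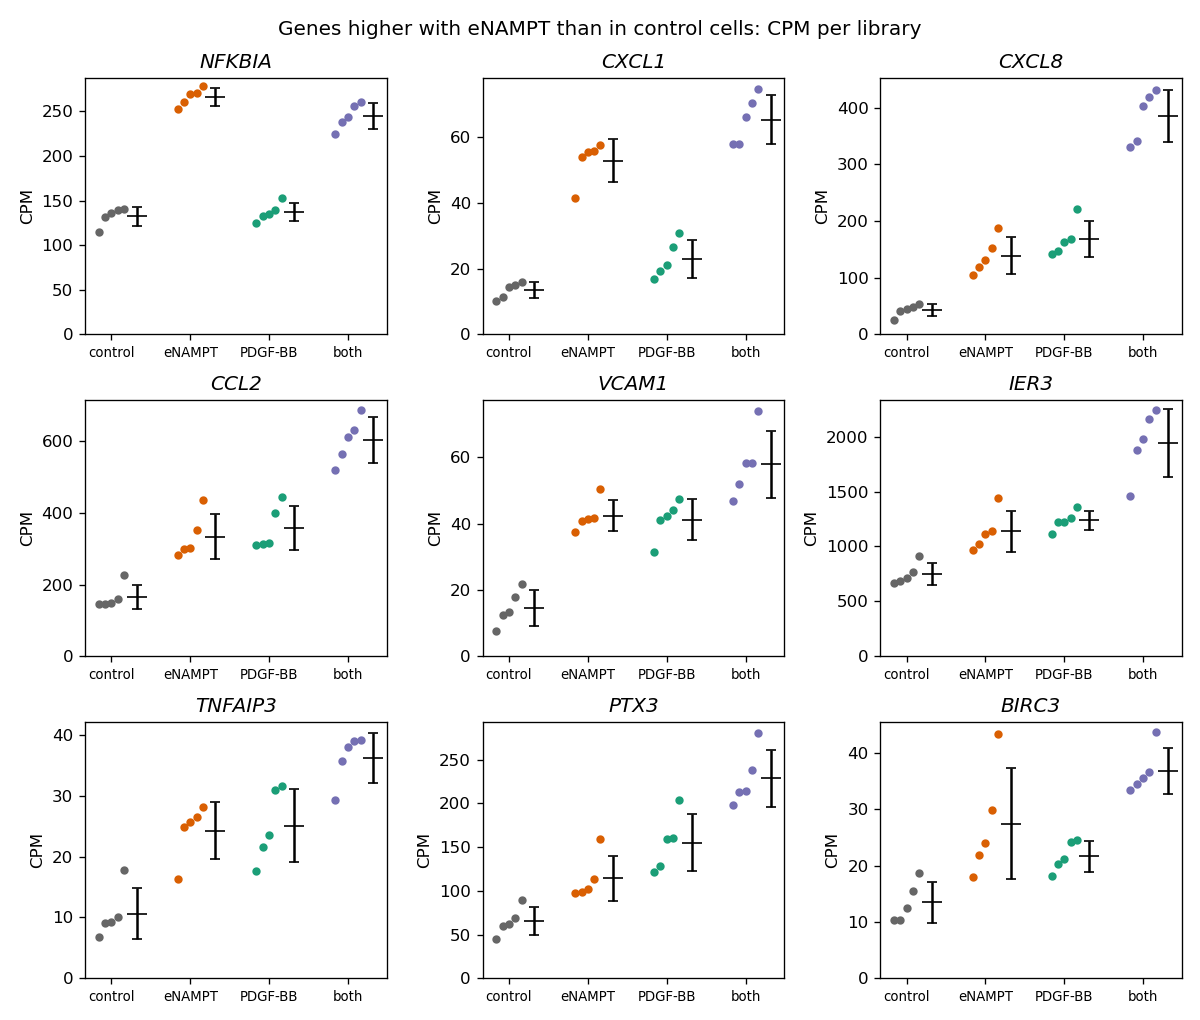
Expression in CPM (vertical axes, linear from 0) of the 9 genes higher with eNAMPT than in control, in the 4 groups, with points for the 5 libraries of a group, sorted by value, and bars for the mean ± SD. NFKBIA stood at 266 CPM with eNAMPT and 137 CPM with PDGF-BB, against 132 CPM in control.

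PDGF-BB alone was compared with control to find the response to the growth factor. Some immediate early, ERK feedback and inflammatory genes rose. EGR1, an immediate early transcription factor (ENSG00000120738, chromosome 5, 138465490 to 138469315), went from 67.0 CPM ± 5.82 (SD, n = 5) to 207 CPM ± 30.2. DUSP6, a phosphatase that acts on ERK, went from 47.6 CPM ± 16.1 to 109 CPM ± 11.7, and PDGFA, which encodes a related growth factor chain, from 117 CPM ± 12.2 to 225 CPM ± 22.6. CXCL8 reached 169 CPM ± 31.6 and the adhesion molecule ICAM1 went from 6.80 CPM ± 2.81 to 23.3 CPM ± 5.99. SIX4, a homeobox transcription factor, fell from 20.6 CPM ± 2.15 to 10.0 CPM ± 1.74.

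With PDGF-BB, 127 genes rose and 20 fell (edgeR quasi-likelihood), with 1168 at an unadjusted p under 0.05. When replicate number was a term in the model, 299 rose and 78 fell. Scaling by spike-in counts, tried after the data were seen, left 40 higher and 0 lower, although the fold changes hardly moved (SIX4 -1.04 to -1.02, ZIC2 -0.62 to -0.61, JMY -0.95 to -0.89). The log2 fold change was 1.63 (SE 0.10, adjusted p 2.68e-15) for EGR1, 2.00 (SE 0.14, 1.79e-13) for CXCL8, 1.76 (SE 0.24, 5.18e-06) for ICAM1, 1.49 (SE 0.17, 8.35e-08) for VCAM1 and 0.94 (SE 0.08, 6.47e-11) for PDGFA. The small GTPase gene RRAD rose by 1.70, TAGLN3 by 1.58 and CD83 by 1.53. Among the genes that fell, SIX4 had a log2 fold change of -1.04 (SE 0.19, adjusted p 0.000691), the actin regulator JMY -0.95 and the transcription factor ZIC2 -0.62. LARGE2 (-2.335, adjusted p 0.0378) and FRAT1 (-1.77, 0.0477) fell by more. Their calls ended in 7 and 9 of the 10 fits without 1 library. Of the 10 largest falls, 6 calls ended in at least 1 such fit, as did 3 of the 10 largest rises. In each gene named here 5 of 5 libraries lay on the same side of the control mean. The naming rule required this of the largest rises and falls. NAMPT itself had a log2 fold change of 0.36 (adjusted p 0.0608).

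Of the 20 tested immediate early genes, 8 rose with PDGF-BB over all genes and 15 when adjusted over the list alone, such as FOSB (1.43) and IER2 (0.58). In the ERK output and feedback list 5 of 17 rose over all genes and 7 over the list alone, among them DUSP6 (1.20), DUSP5 (1.06) and HBEGF (1.01), a ligand of the EGF receptor. In the NF-kB and inflammatory list 13 of 28 rose over all genes and 23 over the list alone, while NFKBIA had a log2 fold change of 0.05 (adjusted p 0.912). In the interferon list 8 of 21 rose over all genes and 13 over the list alone, among them the antiviral genes IFI44L (0.79), MX1 (0.73), RSAD2 (0.71) and GBP1 (0.54). Matrix proteolysis genes rose in 3 of 16 cases over all genes and 5 over the list alone, with the urokinase receptor PLAUR (0.60), the protease ADAMTS1 (0.60) and the protease inhibitor TIMP3 (0.44). Angiogenic factors rose in 5 of 16 cases over all genes, with ANGPTL4 (1.34) and PDGFA, and 7 were higher and 1 lower when adjusted over the list alone.

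The median log2 fold change with PDGF-BB and the adjusted p by camera were 0.43 and 1.31e-18 for the immediate early list, 0.23 and 6.01e-08 for ERK output, 0.86 and 1.63e-34 for NF-kB, 0.36 and 2.58e-14 for interferon, 0.20 and 8.73e-06 for matrix proteolysis and 0.21 and 3.48e-07 for angiogenic factors. With an estimated correlation the adjusted p of these 6 lists was 3.22e-05, 0.0147, 3.82e-06, 0.0458, 0.00323 and 0.00269. Ribosome biogenesis (median 0.12), FOXO targets (-0.21) and glycolysis and hypoxia (0.08) passed with the preset correlation only, with adjusted p of 0.000169, 0.00723 and 0.0249, against 0.164, 0.0570 and 0.0545 with an estimated correlation. Of the FOXO targets, TXNIP, an inhibitor of thioredoxin and glucose uptake, fell by 0.50 on the log2 scale. The FOXO call ended without control replicate 4 (adjusted p 0.0528), and the glycolysis call without control replicate 4 (0.0562), control replicate 5 (0.0970) or PDGF-BB replicate 2 (0.0526). The other 12 lists had adjusted p of 0.054 to 0.924, and of these the ATF4, mitosis and cholesterol lists passed in some fits that left out 1 library: the ATF4 list without control replicate 1 (0.0332), control replicate 3 (0.0292) or PDGF-BB replicate 5 (0.00603), the mitosis list without PDGF-BB replicate 1 (0.0286), PDGF-BB replicate 2 (0.0107), control replicate 3 (0.0292) or control replicate 5 (0.0381), and the cholesterol list without control replicate 1 (0.0296) or PDGF-BB replicate 5 (0.00343).

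Cells given both factors were compared with control to describe the combined response. Several chemokine and cytokine genes rose. CXCL8 reached 385 CPM ± 46.4 (SD, n = 5) against 42.5 CPM ± 10.7 in control, and CCL2 603 CPM ± 63.5 against 166 CPM ± 34.5. The inflammatory cytokine gene IL1B went from 5.70 CPM ± 2.21 to 22.7 CPM ± 5.60. IL6 went from 1.30 CPM ± 0.663 to 8.22 CPM ± 2.96, where the control mean rested on 4.2 counts per library. SMAD6, an inhibitor of BMP signalling, fell from 11.7 CPM ± 1.46 to 5.00 CPM ± 1.58, and LIPE, the hormone-sensitive lipase, from 11.6 CPM ± 3.53 to 5.38 CPM ± 1.27.

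With both factors, 198 genes rose and 42 fell against control (edgeR quasi-likelihood), with 1324 at an unadjusted p under 0.05. When replicate number was a term in the model, 385 rose and 125 fell. Scaling by spike-in counts left 40 higher and 10 lower, and it moved the median of all genes from -0.01 to -0.14, so changes against the other genes are given here. The log2 fold change was 3.19 (SE 0.14, adjusted p 1.07e-20) for CXCL8, 2.62 (SE 0.42, 5.3e-05) for IL6, 2.50 (SE 0.29, 3.64e-08) for CXCL3, 2.29 (SE 0.15, 1.09e-14) for CXCL1 and 2.01 (SE 0.26, 7.31e-07) for IL1B. Among the genes that fell, SMAD6 had -1.21 (SE 0.29, adjusted p 0.0108) and LIPE -1.10 (SE 0.26, 0.0128). FRAT1 (-2.09, adjusted p 0.011), RPS15AP10 (-1.63, 0.0178) and L3MBTL1 (-1.24, 0.045) fell by more. Their calls ended in 1, 3 and 8 of the 10 fits without 1 library. Of the 10 largest falls, 7 calls ended in at least 1 such fit, against 0 of the 10 largest rises. All 5 combined-treatment libraries lay on the same side of the control mean for each of these genes, which the naming rule required of the largest changes. NAMPT rose by 0.39 (SE 0.10, adjusted p 0.022). That call ended without control replicate 3 (0.35, adjusted p 0.0788), 4 (0.38, 0.0637) or 5 (0.36, 0.0593), or the combined group's replicate 2 (0.36, 0.0645) or 4 (0.35, 0.0830).

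Of the NF-kB and inflammatory list, 25 of 28 rose with both factors over all genes and 26 when adjusted over the list alone, with a median of 1.53 (adjusted p 1.12e-64 by camera, 4.38e-08 with an estimated correlation). Immediate early genes rose in 13 of 20 cases over all genes and 17 over the list alone, with EGR1 (1.90), IER3 (1.37) and JUNB (0.95), and a median of 0.61 (1.8e-25, estimated 4.12e-06). ERK output genes rose in 6 of 17 cases over all genes and 9 over the list alone, with a median of 0.31 (2.65e-09, estimated 0.0077). Matrix proteolysis genes rose in 4 of 16 cases, 6 over the list alone (5.96e-06, estimated 0.00372), and angiogenic factors in 5 of 16 cases, with 9 higher and 2 lower over the list alone (4.26e-06, estimated 0.00459). Interferon genes rose in 8 of 21 cases, 14 over the list alone, with a median of 0.45 and an adjusted p of 1.29e-12, but 0.0662 with an estimated correlation. Of the tested epithelial markers, whose median was 0.18, KRT18 rose by 0.39 (adjusted p 0.0154) beside these lists, from 161 CPM ± 16.6 to 211 CPM ± 26.7. Its call ended without control replicate 1 (0.37, adjusted p 0.0533) or 3 (0.35, 0.0650), or the combined group's replicate 4 (0.34, 0.0722) or 5 (0.34, 0.0714).

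Of the genes in lists with smaller shifts, few passed one by one: 1 ribosome biogenesis gene and 1 contractile gene rose, and 1 FOXO target fell. Ribosome biogenesis had a median of 0.14 (adjusted p 0.000103 by camera), FOXO targets -0.21 (0.0199), ATF4 and unfolded protein targets 0.15 (0.0145), contractile genes 0.13 (0.0232), glycolysis and hypoxia 0.07 (0.0385) and mitosis -0.06 (0.0345). With an estimated correlation none of these 6 lists passed, at adjusted p of 0.148, 0.105, 0.269, 0.445, 0.0940 and 0.445. Under spike-in scaling the median of the ATF4 list was -0.01 and that of glycolysis -0.06. When adjusted over the list alone, 3 ribosome biogenesis, 2 contractile and 1 glycolysis gene were higher, and 3 FOXO targets and 1 mitosis gene lower. The ATF4 call ended without control replicate 5 (0.0861) or the combined group's replicate 3 (0.131), and the FOXO call without control replicate 4 (0.0722) or the combined group's replicate 5 (0.0630). The contractile call ended without control replicate 1 (0.135), 2 (0.275) or 3 (0.324), or the combined group's replicate 3 (0.0885), 4 (0.460) or 5 (0.315). The glycolysis call ended without control replicate 4 (0.0722) or 5 (0.151), or the combined group's replicate 1 (0.0850), 2 (0.0567) or 4 (0.0796). The mitosis call ended without control replicate 1 (0.126), 2 (0.0697) or 4 (0.0657), or the combined group's replicate 3 (0.166), 4 (0.0796) or 5 (0.135). The other 9 lists had adjusted p of 0.0589 to 0.891. The lowest was cholesterol synthesis, which passed without control replicate 1 (0.0146) or 4 (0.0383) or the combined group's replicate 5 (0.000391).

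**Figure D2:**
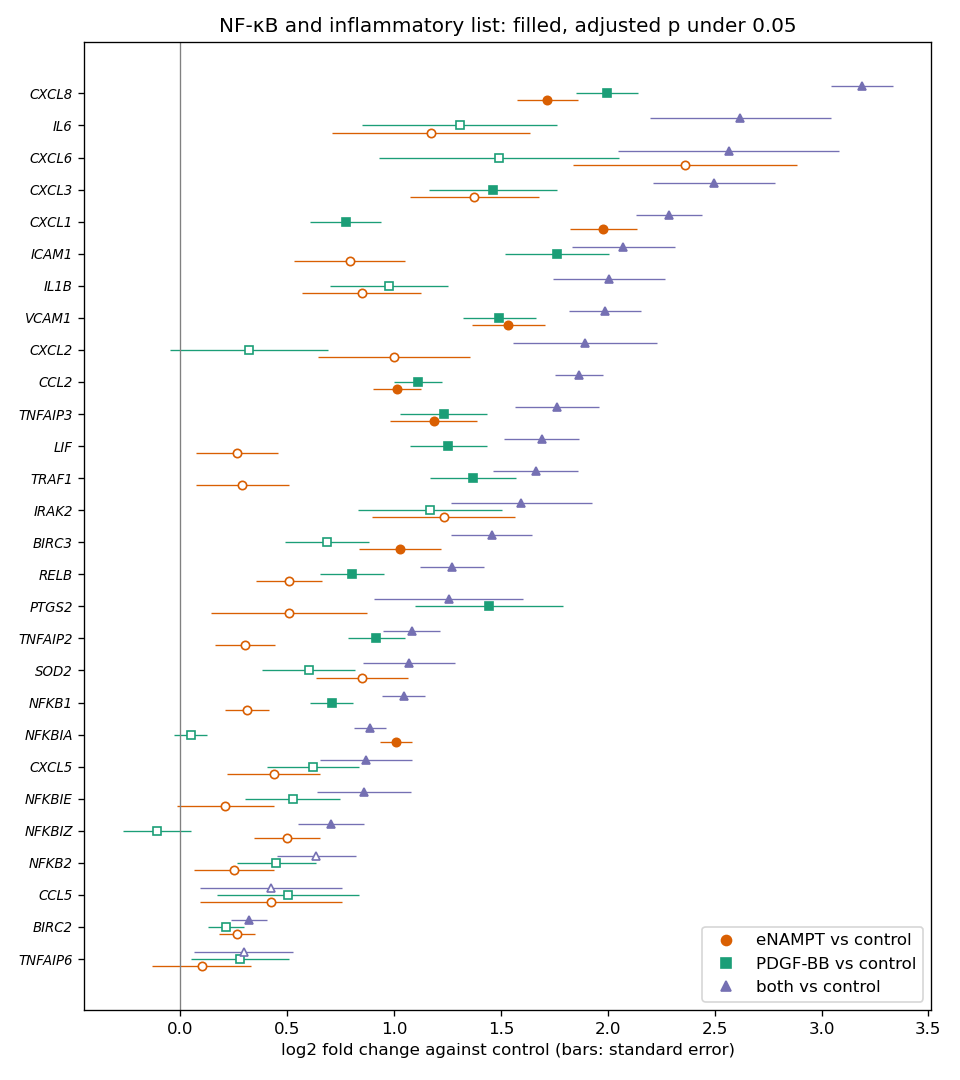
Log2 fold change against control (horizontal axis) of the 28 tested NF-kB and inflammatory genes with eNAMPT (circles), PDGF-BB (squares) and both (triangles), with standard errors from 5 libraries per group as bars and filled symbols for an adjusted p under 0.05. The number passing was 7 with eNAMPT, 13 with PDGF-BB and 25 with both.

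Adding eNAMPT to PDGF-BB tested the eNAMPT effect in cells that also received the growth factor, in libraries separate from those of the first comparison. CXCL1 went from 22.9 CPM ± 5.69 (SD, n = 5) with PDGF-BB to 65.3 CPM ± 7.48 with both, and CXCL8 from 169 CPM ± 31.6 to 385 CPM ± 46.4. NFKBIA went from 137 CPM ± 10.4 to 245 CPM ± 14.3 and CCL2 from 357 CPM ± 61.3 to 603 CPM ± 63.5. IER3 went from 1237 CPM ± 88.9 to 1942 CPM ± 308.

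Against PDGF-BB alone, 7 genes rose and 0 fell (edgeR quasi-likelihood), with 412 at an unadjusted p under 0.05, fewer than the 606 expected if no gene differs. With replicate number as a term in the model, 15 genes passed and 657 had an unadjusted p under 0.05. DESeq2 passed 11 and limma-voom 9, all higher, and scaling by spike-in counts, which moved the median of all genes to -0.15, left 2. The log2 fold change was 1.51 (SE 0.14, adjusted p 1.46e-09) for CXCL1, 1.19 (SE 0.13, 2.24e-08) for CXCL8, 0.84 (SE 0.08, 5.85e-10) for NFKBIA, 0.76 (SE 0.11, 4.07e-05) for CCL2 and 0.65 (SE 0.09, 3.88e-05) for IER3. These 5 genes also rose with eNAMPT in the absence of PDGF-BB. NFKBIZ, an atypical NF-kB inhibitor protein, rose by 0.81 (SE 0.15, 0.00759), a call that ended without the combined group's replicate 2 (0.76, adjusted p 0.0601), PDGF-BB replicate 3 (0.73, 0.0760) or PDGF-BB replicate 4 (0.76, 0.0553). The chemokine CXCL2 rose by 1.57 (SE 0.32, 0.0317), a call that held only when the library left out was the combined group's replicate 5; without any other single library the value was 1.41 to 1.66. In each of the 7 genes, 5 of 5 libraries lay above the PDGF-BB mean.

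In the NF-kB and inflammatory list, 6 of 28 rose on adding eNAMPT to PDGF-BB over all genes and 17 when adjusted over the list alone. The median was 0.47, with an adjusted p of 5.43e-31 by camera and 7.9e-06 with an estimated correlation. In the immediate early list IER3 alone rose of 20 genes over all genes and 3 over the list alone, with a median of 0.16 that was -0.01 under spike-in scaling. Its adjusted p was 4.51e-05, and 0.0287 with an estimated correlation. The other 19 lists had adjusted p of 0.452 to 0.996, of which the cholesterol list passed without the combined group's replicate 5 (0.0450).

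Adding PDGF-BB to eNAMPT tested the PDGF-BB effect in cells that also received eNAMPT. DUSP6 went from 37.5 CPM ± 9.61 (SD, n = 5) with eNAMPT to 125 CPM ± 8.55 with both. EGR1 went from 91.8 CPM ± 13.1 to 250 CPM ± 27.1, PDGFA from 106 CPM ± 7.54 to 227 CPM ± 6.07, and IL11, a cytokine of the interleukin 6 family, from 91.3 CPM ± 8.57 to 254 CPM ± 57.7. SMAD6 went from 12.2 CPM ± 3.22 to 5.00 CPM ± 1.58.

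Against eNAMPT alone, 143 genes rose and 42 fell (edgeR quasi-likelihood), with 1316 at an unadjusted p under 0.05, and 24 and 7 under spike-in scaling, which moved the median of all genes to -0.14. When replicate number was a term in the model, 359 rose and 152 fell. The log2 fold change was 2.14 (SE 0.29, adjusted p 2.31e-06) for TAGLN3, 1.73 (SE 0.15, 4.32e-11) for DUSP6, 1.71 (SE 0.15, 6.56e-11) for the secreted lipase inhibitor ANGPTL4, 1.48 (SE 0.14, 5.1e-10) for IL11 and 1.45 (SE 0.10, 6.33e-14) for EGR1. The cytokine gene LIF rose by 1.43, TRAF1, an adaptor of TNF receptors, by 1.37, and CXCL8 by 1.47. Among the genes that fell, the polarity gene PARD6B had -1.79 (SE 0.42, adjusted p 0.0113), SMAD6 -1.28 (SE 0.29, 0.00703), ID2 -1.11 (SE 0.18, 0.000119) and ID3 -0.39 (SE 0.07, 0.000932). Of the 10 largest falls, 6 calls ended in at least 1 fit without 1 library, but not those of PARD6B, SMAD6 and ID2. ID2 and ID3 encode inhibitors of DNA binding and are targets of BMP signalling. ID2, and the IER2 and NAMPT values given elsewhere, are less certain, since their counts here were 73.8%, 63.7% and 67.1% of those in the other count table. All 5 combined-treatment libraries lay on the same side of the eNAMPT mean for each gene, which the naming rule required of the largest changes.

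Of the immediate early list 11 of 20 rose against eNAMPT alone over all genes and 17 over the list alone, with DUSP1 (1.21) and IER2 (0.88). In the ERK output list 8 of 17 rose over all genes and 10 over the list alone, with SPRY4 (1.09), an inhibitor of receptor tyrosine kinase signalling. In the NF-kB and inflammatory list 11 of 28 rose over all genes and 18 over the list alone. Matrix proteolysis genes rose in 5 of 16 cases, 8 over the list alone, and angiogenic factors in 6 of 16, with 9 higher and 1 lower over the list alone, among them ANGPTL4. The medians of these 5 lists were 0.58, 0.47, 0.61, 0.38 and 0.39. Their adjusted p was 2.18e-23, 4.23e-14, 3.39e-20, 9.77e-08 and 8.79e-07 by camera, and 1.34e-05, 0.00132, 6.68e-05, 0.000789 and 0.00217 with an estimated correlation. TGF-beta and BMP targets did not pass as a list (adjusted p 0.479), with 4 of 18 higher and 3 lower over all genes, and 4 higher and 4 lower over the list alone. The epithelial marker KRT18 rose beside these lists by 0.49 (SE 0.10, adjusted p 0.00136), from 150 CPM ± 19.5 to 211 CPM ± 26.7. The median of the tested epithelial markers was 0.37.

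Of the interferon list 1 of 21 genes rose against eNAMPT alone over all genes and 10 over the list alone, with a median of 0.34 (adjusted p 1.33e-06 by camera, 0.190 with an estimated correlation). Ribosome biogenesis had a median of 0.14 (0.000126, estimated 0.155), FOXO targets -0.20 (0.00319, estimated 0.05), Notch 0.20 (0.0250, estimated 0.0580), glycolysis and hypoxia 0.08 (0.0203, estimated 0.0543), contractile genes 0.11 (0.0203, estimated 0.404), ATF4 targets 0.11 (0.0254, estimated 0.319) and mitosis -0.07 (0.0175, estimated 0.319). Under spike-in scaling the median was -0.01 for contractile genes, -0.04 for ATF4 targets and -0.06 for glycolysis. In these 7 lists, 1 ribosome biogenesis and 1 glycolysis gene rose over all genes and 1 mitosis gene fell. Over the list alone 3 ribosome biogenesis, 3 contractile, 1 glycolysis and 1 Notch gene were higher, and 3 FOXO targets and 1 mitosis gene lower. The mitosis call ended without eNAMPT replicate 1 (0.0639) or the combined group's replicate 3 (0.0943) or 5 (0.0663), and the ATF4 call without eNAMPT replicate 5 (0.154) or the combined group's replicate 3 (0.248). The contractile call ended without eNAMPT replicate 1 (0.0596), 2 (0.190) or 3 (0.151), or the combined group's replicate 4 (0.280) or 5 (0.174). The Notch call ended without eNAMPT replicate 1 (0.0654), 2 (0.0644), 4 (0.0541) or 5 (0.0522), or the combined group's replicate 4 (0.141) or 5 (0.0529). The other 8 lists had adjusted p of 0.115 to 0.917, and of these cholesterol synthesis passed without eNAMPT replicate 4 (0.0477) or the combined group's replicate 5 (0.00144).

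**Figure D3:**
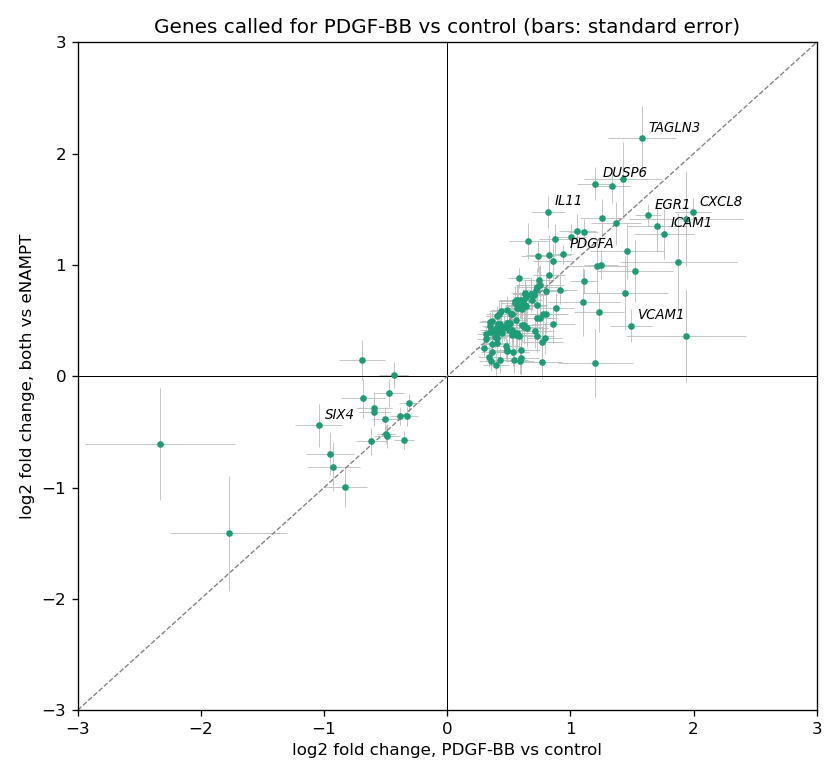
Log2 fold changes of the 147 genes that passed for PDGF-BB against control (horizontal axis), set against those of both factors over eNAMPT alone (vertical axis), with standard errors from 5 libraries per group as bars and a dashed line for equal values. The sign was the same in 145 of the 147 genes.

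The interaction tested whether the eNAMPT effect differed with PDGF-BB present. VCAM1 had the smallest p: its level was 42.4 CPM ± 4.76 (SD, n = 5) with eNAMPT, 41.2 CPM ± 6.06 with PDGF-BB and 57.8 CPM ± 10.1 with both, less than the sum of the single effects on the log2 scale. Its interaction was -1.04 (SE 0.23, unadjusted p 4.32e-05), with an adjusted p of 0.523 over all genes and 0.00121 over the NF-kB and inflammatory list alone. CXCL8 had -0.52 (SE 0.19, adjusted p 0.999) and NFKBIA -0.17 (SE 0.11, 95% interval -0.38 to 0.04, 0.999). IL11 had 0.66 (SE 0.20, 0.999). These calls depended on the model. With replicate number as a term, the interaction was 0.62 for IL11 (edgeR adjusted p over all genes 0.000968), -1.05 for VCAM1 (0.002) and -0.50 for CXCL8 (0.0451).

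In the interaction 0 genes passed over all genes with edgeR, with DESeq2 and with limma-voom, and 406 had an unadjusted p under 0.05 (edgeR), where 606 are expected if no gene differs. With replicate number as a term in the edgeR model, 662 had an unadjusted p under 0.05. Some alternative fits passed a few genes, up to 7 with replicate number as a term, given with the other effects of processing. At list level, the NF-kB and inflammatory list had a negative median interaction (-0.18, adjusted p 0.0126 by camera, 0.627 with an estimated correlation), and -0.36 under spike-in scaling, which moved the median of all genes to -0.16. The ERK output list had a median of 0.20 (0.0244, estimated 0.692), which was -0.01 under spike-in scaling, and the interferon list -0.14 (0.0401, estimated 0.898), which was -0.29. The NF-kB call ended without control replicate 4 (adjusted p 0.138) or the combined group's replicate 5 (0.0518). The ERK call ended without control replicate 1 (0.1) or 3 (0.126), eNAMPT replicate 4 (0.264), PDGF-BB replicate 3 (0.0894) or the combined group's replicate 1 (0.0584), 2 (0.0533) or 5 (0.0518). The interferon call ended without control replicate 3 (0.466) or 5 (0.194), eNAMPT replicate 1 (0.125), 2 (0.197) or 4 (0.264), PDGF-BB replicate 1 (0.140), 2 (0.114) or 4 (0.328), or the combined group's replicate 3 (0.208) or 5 (0.477). The other 18 lists had adjusted p of 0.13 to 0.975.

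Each factor's effect was measured in separate libraries with and without the other factor, so its recurrence could be tested across 12111 genes, which are not independent replicates. All 9 genes that passed with eNAMPT had the same sign when it was added to PDGF-BB, and 5 of them, CXCL1, CXCL8, CCL2, NFKBIA and IER3, passed there too. Across all genes the eNAMPT effects had a Pearson r of 0.03 (permutation p 0.21, Benjamini-Hochberg adjusted 0.21 over 2 correlations) and a Spearman rho of -0.01 (permutation p 0.53). For the PDGF-BB effects 145 of 147 genes had the same sign and 92 passed both times. Their r was 0.34 (permutation p 0.01, adjusted 0.02) and rho 0.29 (permutation p 0.01), where 0.01 is the smallest p that the 100 permutations can give.

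The genes that rose with each factor alone overlapped. CXCL1, CXCL8, CCL2, VCAM1, TNFAIP3, PTX3 and IER3 passed with eNAMPT and with PDGF-BB, 7 of the 9 and 147 genes, and 0 genes fell with both. These comparisons share their 5 control libraries. Independent lists of the 9 and 127 genes that rose would share 0.0944 genes. When the control libraries were divided between the comparisons, 5 genes were shared in each of 2 divisions. Across all genes the fold changes had a covariance of 0.0288, against 0.0272 simulated from shared controls without effect, and with divided controls it was -0.00143 and -0.00691. The divisions set control replicates 1 and 2 against 3, 4 and 5. Libraries of the same number were somewhat alike, so dividing them this way can by itself lower the covariance. The simulation held no variation by replicate number. These covariances therefore cannot tell whether the factors share a wider response.

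Several lists passed in none of the 6 comparisons by camera. The adjusted p ranged over the comparisons from 0.0589 to 0.985 for cholesterol synthesis, 0.183 to 0.985 for entry into S phase, 0.256 to 0.996 for pericyte markers, 0.479 to 0.985 for extracellular matrix, 0.891 to 0.987 for NAD metabolism, 0.204 to 0.924 for receptors, 0.479 to 0.985 for TGF-beta and BMP targets and 0.393 to 0.985 for fibroblast markers. Single members passed all the same, such as the matrix glycoprotein TNC, which rose by 0.53 with PDGF-BB (adjusted p 0.00129). The endothelial and leukocyte lists had 4 tested members each and the epithelial and neural or glial lists 2 each, too few for a test. The median, the mean and the camera direction had the same sign in all 41 cases in which a list passed a comparison, and differed in 26 of the 85 other cases.

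The authors' own fold changes in the deposited table passed similar numbers of genes at an adjusted p under 0.05: 8 with eNAMPT, 162 with PDGF-BB and 247 with both against control, 9 for both against PDGF-BB and 205 for both against eNAMPT. Of these, 8, 137, 227, 7 and 177 also passed here, all in the same direction. For all 8 genes with eNAMPT and all 9 for both against PDGF-BB, the authors' fold changes were smaller than those here. With eNAMPT they were 1.33 for CXCL1, 0.94 for NFKBIA, 0.94 for VCAM1, 0.63 for TNFAIP3 and 0.57 for BIRC3. The values here were 1.98, 1.01, 1.53, 1.19 and 1.03. For CXCL2 with both against PDGF-BB the authors had 0.59, against 1.57. It was not examined whether the authors' values were shrunk towards 0. They may therefore be a different measure, and the gap need not be a disagreement on the size of the effects.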

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

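The tests of linear addition, of 1 library, of the correlation among list genes, of shared control libraries and of endotoxin were chosen only after the result was seen. The groupings of the same libraries were chosen before.

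The interaction singled out 3 lists as differing between groups, at adjusted p of 0.0126 for the NF-kB and inflammatory list, 0.0244 for ERK output and 0.0401 for interferon (camera, preset correlation). Of these 3 lists 0 passed with an estimated correlation. The NF-kB list had a median interaction of -0.18 on the log2 scale (jackknife SE 0.098), within 2 SE of 0, so the absence of a difference on that scale is left open. With an estimated correlation the adjusted p was 0.627, so correlation among the list's genes could account for the call. That correlation was estimated without replicate number as a term, so the likeness of libraries by number may enter it. If the treatments add on the linear scale, the median of the log2 ratio of the level with both to that sum would be 0, and it was 0.0403 (jackknife SE 0.0914), which leaves linear addition open. Leaving out 1 library brought the median no nearer to 0 than -0.118, which argues against 1 library making its size, although the call itself ended without control replicate 4 or the combined group's replicate 5.

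The 7 genes that rose with eNAMPT and with PDGF-BB were also tested for an overlap made by the 5 control libraries used in both comparisons. With separate control libraries 5 genes were still shared, the lower of 2 divisions, which argues against that explanation.

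The NF-kB genes that rose with eNAMPT might reflect endotoxin carried by the recombinant protein, since TLR4 is the receptor of endotoxin and its transcript was counted. Endotoxin can induce interferon genes. The adjusted p of the interferon list with eNAMPT was 0.762 with an estimated correlation. This cannot tell endotoxin from eNAMPT, because not every cell type makes interferon in reply to endotoxin and eNAMPT is itself described as acting on TLR4.

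Libraries were regrouped at random in 100 ways per comparison, the real one included. As many genes passed as in the real grouping in 3 of 100 for eNAMPT against control (real 9, highest other 43), 1 for PDGF-BB (147, 35), 1 for both against control (240, 69), 2 for both against PDGF-BB (7, 18), 1 for both against eNAMPT (185, 72) and 100 for the interaction (0, 35). The 100 for the interaction was fixed in advance and tests nothing, because any grouping reaches a real count of 0. The groupings with 43 and 18 put low replicate numbers of both groups together. For gene lists, as many passed in 47 of 100 for eNAMPT (real 2, highest other 7), 5 for PDGF-BB (9, 10), 2 for both against control (12, 13), 63 for both against PDGF-BB (2, 8), 1 for both against eNAMPT (13, 12) and 34 for the interaction (3, 9). For the list counts of eNAMPT, PDGF-BB, both against PDGF-BB and the interaction, chance therefore cannot be excluded. At least 1 list passed in 75, 90, 92, 83, 87 and 77 of the other groupings of these comparisons, in the same order. The median there was 1, 3, 3, 2, 3 and 2 lists. Some of these groupings keep part of a treatment difference. Even so, an adjusted p by camera with the preset correlation is weak evidence on its own.

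In 18 of 256 groups of 5 libraries, 1 library stood far from the others, by a gap to its neighbour over the range above the Dixon limit. Chance alone gives about 1 in 20, or 12.8 here. All libraries were kept.

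Among library measures, the ratio was 0.717 for the spike-in share in PDGF-BB replicate 5, 0.731 for the mitochondrial share in eNAMPT replicate 4 and 0.722 for the share of the 10 largest genes in eNAMPT replicate 4.

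In the eNAMPT group replicate 4 was low for CXCL1 (ratio 0.785, 41.4 CPM against 53.96 to 57.4 in the others) and TNFAIP3 (0.721, 16.3 against 24.8 to 28.1). Replicate 5 was high for PTX3 (0.754, 159 against 98.0 to 113), HBEGF (0.763, 153 against 81.8 to 98.7) and ADAMTS1 (0.721, 232 against 146 to 170).

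In the control group replicate 5 was high for CCL2 (0.797, 226 CPM against 145 to 161), replicate 1 low for EGR1 (0.733, 56.9 against 67.0 to 70.7) and replicate 3 low for ID3 (0.810, 242 against 315 to 332). Replicate 4 was low for IL1B (0.794, 1.87 against 6.12 to 7.22) and high for ATOH8 (0.756, 22.7 against 14.5 to 16.5).

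With PDGF-BB, replicate 3 was low for SIX4 (0.722, 7.02 CPM against 10.1 to 11.2) and replicate 4 high for MYC (0.770, 48.1 against 33.4 to 36.8). With both, replicate 3 was low for PDGFA (0.747, 216 against 228 to 232), replicate 2 high for ID2 (0.718, 26.8 against 14.8 to 18.1) and replicate 5 high for PARD6B (0.773, 3.29 against 1.29 to 1.75).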

How the results depend on the processing

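No named gene that passed changed its direction under spike-in scaling. Spike-in scaling, the other count table and the single-library omissions for lists and overlap were tests chosen only after the result was seen. Where no reason is given for a change, the cause was not tested.

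RLE size factors and limma-voom kept the gene counts of all comparisons within 1.5 times. The eNAMPT count of 9 was 14 with DESeq2 (13 higher, 1 lower), 14 without the low-count filter (13 and 1) and 21 with replicate number as a term (18 and 3). Leaving out 1 library gave 8 to 13.

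The PDGF-BB count of 147 was 40 under spike-in scaling (40 higher, 0 lower), 377 with replicate number (299 and 78), and, as stricter limits must lower it, 88 at an adjusted p under 0.01 and 29 at an absolute log2 fold change of at least 1. Without 1 library it was 104 to 137.

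The count of 240 for both against control was 50 under spike-in scaling (40 and 10), 510 with replicate number (385 and 125), 137 at 0.01 and 52 at a change of at least 1. Leaving out 1 library gave 180 to 250.

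The count of 7 for both against PDGF-BB was 11 with DESeq2, 12 without the filter, 15 with replicate number (13 and 2), 11 with only the groups compared, 2 under spike-in scaling and 3 at a change of at least 1. Fits without 1 library gave 5 to 7.

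The count of 185 for both against eNAMPT was 31 under spike-in scaling (24 and 7), 511 with replicate number (359 and 152), 117 at 0.01 and 32 at a change of at least 1. Leaving out 1 library gave 143 to 200.

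The interaction count of 0 was 3 without the filter, 7 with replicate number (1 and 6, among them IL11, VCAM1 and CXCL8), 1 without control replicate 1 and 0 without any other library, such as eNAMPT replicate 1.

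Replicate numbers were not treated as pairs, since the labels do not say that a number marks libraries made together. Residual correlations of libraries with the same number were 0.0143 to 0.252 (median 0.153, other numbers -0.0377), and 18 of 20 libraries were closest to their own number. Libraries of the same number were thus somewhat alike. Every gene count above was higher with replicate number as a term, so the counts of the main fit depend on this choice. For eNAMPT, both against PDGF-BB and the interaction, the main fit had 437, 412 and 406 genes at an unadjusted p under 0.05. That is short of the 606 expected if no gene differs, and the term brought them to 659, 657 and 662. A gene that did not pass in the main fit, the interaction included, is therefore not shown to be unchanged.

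With an estimated correlation the lists passing went from 2 to 1 for eNAMPT, 12 to 5 for both against control, 13 to 5 for both against eNAMPT and 3 to 0 for the interaction. With fry they were 1 for eNAMPT and 0 for the interaction. Leaving out 1 library gave 1 (without control replicate 3) to 3 (without control replicate 4) for eNAMPT, and 0 (without the combined group's replicate 5) to 3 (without control replicate 2) for the interaction.

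Spike-in scaling, which shifts all genes of the combined group down and so must carry small medians past 0 without bearing on a list relative to other genes, turned the median of immediate early genes from 0.16 to -0.01 against PDGF-BB and of ERK output from 0.20 to -0.01 in the interaction. Against control ATF4 targets went from 0.15 to -0.01 and glycolysis from 0.07 to -0.06. Against eNAMPT contractile genes went from 0.11 to -0.01, ATF4 targets from 0.11 to -0.04 and glycolysis from 0.08 to -0.06.

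The correlation of eNAMPT effects, 0.03, was 0.436 in genes passing in either comparison, a choice that keeps large effects. That of PDGF-BB effects, 0.34, was 0.468 at a mean log2 CPM of at least 3 and 0.839 in genes passing in either. The overlap of 7 genes was 14 with replicate number.

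With 2894878 to 4011066 gene counts per library, depth limits genes such as IL6, at 4.2 counts per control library.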

Other observations

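The comparison of eNAMPT directly with PDGF-BB was among the tests chosen only after the result was seen, and the test of BMP targets was chosen before its result.

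Within the NF-kB and inflammatory list the single treatments differed gene by gene (edgeR quasi-likelihood, 28 genes). Over all genes 3 were higher with eNAMPT and 5 with PDGF-BB. NFKBIA was higher with eNAMPT by 0.96 on the log2 scale (SE 0.08, adjusted p 3.46e-12 over all genes, 1.6e-14 over the list alone), CXCL1 by 1.21 (SE 0.14, 2.24e-07, list alone 2.85e-09) and NFKBIZ by 0.61 (SE 0.15, 0.0359, list alone 0.00106). Relative to PDGF-BB, eNAMPT gave -1.08 for TRAF1 (SE 0.20, 0.000664, list alone 1.46e-05), -0.99 for LIF (SE 0.17, 0.000466, list alone 1.11e-05) and -0.97 for ICAM1 (SE 0.23, 0.0165, list alone 0.000495). Leaving out any 1 of the 10 libraries kept the adjusted p over the list alone at or below 0.00797 for these 6 genes.

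Lower BMP signalling with PDGF-BB was tested as a hypothesis, because ID2, SMAD6, BMP4 and ATOH8 had negative log2 fold changes with it. Against control only BMP4 of these passed, and that call depended on each of 4 of the 10 libraries. On top of eNAMPT all 4 passed, ID2 and SMAD6 whichever library was left out, while the calls of BMP4 and ATOH8 depended on each of 8 and 6 of the 10 libraries. In 6 other BMP targets (ID4, SMAD9, MSX1, MSX2, DLX2 and SMURF1) the median log2 fold change was -0.06 against control and -0.22 on top of eNAMPT, with fry p of 0.797 and 0.487. MSX1 rose by 0.38 on top of eNAMPT (adjusted p 0.00359). These 6 genes cannot tell whether BMP signalling was lower.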
